A study of Homo sapiens with 10 samples.

How the data were processed

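RNA sequencing libraries of hTERT RPE-1 cells were grouped by treatment (control or siNemp1) and substrate stiffness (10 or 120 kPa) from their titles, which also gave the replicate numbers. Per the labels, total RNA was depleted of ribosomal RNA with an RNase H method, reverse transcribed from random hexamers and ligated to Illumina adapters, and strandedness is not given in the sources used here. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.33, Salmon 1.80 (version as written there), edgeR without a version, and the GRCh38 build. The transcript annotation behind the quantification and the step from transcripts to genes are not given in the sources used here.

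The deposited table holds expected counts, that is estimated read counts per gene before any scaling between libraries, for 40664 gene rows in 10 libraries, with totals of 17.9 to 23.8 M per library. All 10 columns matched a library by name. The estimated counts were rounded to whole numbers. Gene positions, lengths and GC content came from GENCODE 29 on GRCh38 and were matched by Ensembl identifier. Of 13990 tested genes 13826 (98.8%) had a length and GC value. Both values are medians over all annotated transcripts of a gene, which can be far from those of the transcript expressed.

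Genes were filtered with edgeR's filterByExpr over the 4 groups, which left 13990. Libraries were scaled with TMM, and 1 quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 10 libraries in edgeR 4.0.16 (limma 3.58.1, R 4.3.3), leaving 6 residual degrees of freedom. The contrasts were siNemp1 against control at 120 kPa and at 10 kPa, 120 kPa against 10 kPa in control and in siNemp1 cells, the difference between the knockdown effects, and the averages of the knockdown and of the stiffness effects. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over all tested genes, with an adjusted p under 0.05 called. CPM values are counts per 1000000 with TMM scaling, given as mean ± SD over the libraries of a group, and log2 fold changes are given with the standard error of the fit.

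The comparisons, the test, the filter, the alternatives except those named as added, the gene lists and the rule for named genes were set before the data were examined. The rule took NEMP1 and NEMP2, up to 10 of the largest rises and 10 of the largest falls among called genes with a mean of at least 5 CPM, a standard symbol and no overlap between the groups (5 and 5 for the difference between stiffnesses, without the last condition), the 4 members with the smallest p of each list that passed or had at least 3 called members, and 15 fixed genes in every comparison. Some genes taken by this rule are not reported here. Of 28 lists with 716 symbols, 697 of which were in the table, the 27 with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, with p-values adjusted over the lists of a contrast, and again with an estimated correlation. No list passed at an adjusted p under 0.05 with the estimated correlation. Members of a list were also counted adjusted over the list alone.

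Whether replicate numbers pair the libraries was checked before calls were compared, by correlating across genes the deviations of same-numbered control and siNemp1 libraries from their group means. The correlation was 0.426, 0.157 and 0.359 for replicates 1, 2 and 3 at 120 kPa and 0.0171 at 10 kPa, and it averaged −0.0461 between stiffnesses. The rule that all of at least 3 pairs exceed 0.1 was met at 120 kPa. The pairing comes from the data and from the numbers in the titles, and what a number stands for is not given in the sources used here. The fit with the replicate number as a block, set in advance and with 4 residual degrees of freedom, is therefore given beside each result whose call it changed. The block assumes that a number means the same at both stiffnesses, which the mean of −0.0461 does not bear out. Replicate 3 exists only at 120 kPa, so its term takes up the mean level of that pair. Blocked contrasts between stiffnesses thus rest mainly on replicates 1 and 2. Another fit set in advance took only the libraries of the groups compared.

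Further alternatives were DESeq2 1.42.0 (23537 genes with a p-value, its own independent filtering in place of filterByExpr), DESeq2's size factors or upper-quartile scaling in edgeR, no filter on low counts, a filter of at least 5 CPM in at least 2 libraries, a log2 fold change of at least 1, and each library left out in turn. After the data were seen, fits with the block at 120 kPa only, with length and GC trends of each library removed as offsets (mgcv 1.9.3), with each pair at 120 kPa left out, and with other scalings in the blocked fit were added, as was DESeq2 on the genes of the edgeR fit. The fits were tested on simulated data in which 100 genes were changed by a log2 fold change of 1 and 100 by 2. Each gene had the same dispersion in all libraries fitted, and the simulation without the block had no replicate effects. Recovery in the real libraries, which spread more at 120 kPa than at 10 kPa, may thus differ. At 120 kPa 58.0% and 96.0% were recovered without the block and 76.0% and 97.0% with it, and at 10 kPa 36.0% and 86.0% in the fit of all libraries and 87.0% and 97.0% in that of the 4 libraries there, with 7 to 17 false calls. Counts below the filter were left out of the tests, and no genotype, isoform or sequence was analysed here.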

Results

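Total RNA was sequenced from hTERT RPE-1 cells, a human retinal pigment epithelial line immortalised with telomerase. They were grown on a soft (10 kPa) or a stiff (120 kPa) substrate, either as controls or treated with siNemp1, a small interfering RNA against NEMP1. NEMP1 is a membrane protein of the inner nuclear envelope. The 10 libraries comprised 2 control and 2 siNemp1 libraries at 10 kPa, and 3 control and 3 siNemp1 libraries at 120 kPa. Their totals ran from 17.9 to 23.8 M estimated counts (M for 1000000). Of 40664 genes in the deposited table, 13990 passed the filter on low counts and were tested. Replicates differed by more than sampling noise, with a chi-square per gene of 2.71 between the control libraries at 10 kPa, 7.78 between the siNemp1 libraries at 10 kPa and 27.0 to 120.1 between pairs of replicates at 120 kPa. Nothing in the labels says that the replicates came from separate cultures, so all p-values measure only the spread between these libraries, which may be technical.

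NEMP1 (ENSG00000166881, chromosome 12, 57055643 to 57088063, minus strand, GRCh38) was lower in each of the 5 siNemp1 libraries than in each of the 5 control libraries. Its level at 10 kPa was 14.1 and 17.3 counts per 1000000 (CPM) in control and 8.22 and 7.63 in siNemp1. At 120 kPa it was 18.3, 14 and 14.1 CPM in control and 7.52, 6.70 and 4.11 in siNemp1. Averaged over both stiffnesses it fell by 1.16 on the log2 scale (SE 0.18), with an adjusted p of 0.044 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At 120 kPa its adjusted p was 0.057 without and 0.0057 with the replicate number as a block, and at 10 kPa 0.80 in the fit of all libraries and 7.3e-05 in the fit of the 4 libraries there. Its paralog NEMP2 lay at 4.94 ± 0.458 CPM in control and 5.65 ± 0.229 in siNemp1 at 120 kPa (mean ± SD, n = 3 each), a log2 difference of 0.20 ± 0.17 that did not pass.

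**Figure D1:**
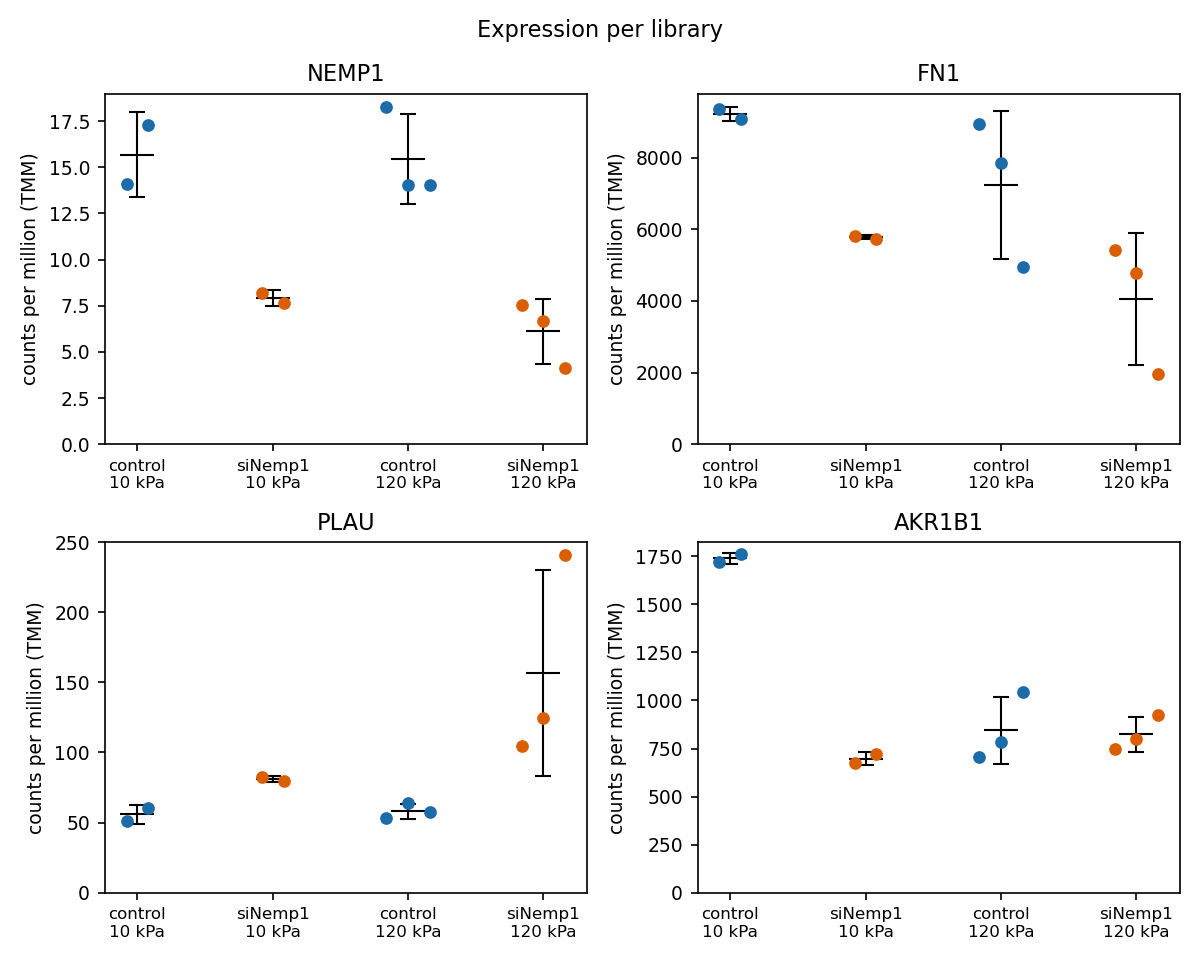
Expression of NEMP1, FN1, PLAU and AKR1B1 in counts per 1000000 with TMM scaling, 1 point per library, with the group mean and SD as black bars (n = 2 per group at 10 kPa and 3 at 120 kPa). NEMP1 ranges from 4.11 to 8.22 in siNemp1 and from 14 to 18.3 in control libraries.

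The first comparison asked which transcripts differ under siNemp1 on the stiff substrate. FN1 (chromosome 2, 215360440 to 215436172), which encodes the matrix protein fibronectin, lay at 4050.0 ± 1849.8 CPM in siNemp1 against 7233 ± 2064 in control cells (mean ± SD, n = 3 each), and the proliferation marker MKI67 at 47.8 ± 14.9 against 83.1 ± 8.40. The protease urokinase, PLAU (chromosome 10, 73909177 to 73917497), lay at 157 ± 73.4 against 58.2 ± 5.42 CPM, and the glycolytic enzyme PGK1 at 1458 ± 315 against 898 ± 64.9. The mitochondrially encoded complex I subunit MT-ND4 lay at 789.9 ± 131 against 1231 ± 336. These genes passed the test in the fit with the replicate number as a block, in which edgeR's quasi-likelihood test called 1224 of 13990 genes at a Benjamini-Hochberg adjusted p under 0.05, 873 higher and 351 lower in siNemp1. With upper-quartile scaling in that fit, a setting added after the data were seen, it called 1215, 645 higher and 570 lower. Without the block edgeR called 0 genes, with 2413 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0511. DESeq2, as set in advance, gave 23537 genes a p-value, before its own filter can narrow those adjusted over. It called 642, 453 higher and 189 lower. On the genes of the edgeR fit, a setting added after the data were seen, it called 723, 500 higher and 223 lower. Without a filter edgeR called 643. Libraries with the same number deviated together at 120 kPa (r = 0.426, 0.157 and 0.359 across genes, which are not independent replicates). A fit of only the 2 groups compared, set in advance and without the block, called 0 of 13362 genes. The fit of all libraries without the block was the main one set in advance. The values that follow are from the blocked fit, an alternative also set in advance, which called more genes.

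Among called genes with a mean of at least 5 CPM and no overlap between the groups, the largest rises at 120 kPa were PLAU (log2 change 1.34 ± 0.21, ± SE), ANKRD46, the histone gene H4C14, CHIC2, the acyl-protein thioesterase LYPLA1 (1.09 ± 0.11), the tyrosine phosphatase PTPRR (1.06 ± 0.13), the lectin-like receptor CD69, TMEM267, the selenoprotein SELENOT (0.98 ± 0.12) and ZNF627 (0.93 ± 0.17). The largest falls were NEMP1 itself (−1.37 ± 0.18), the nuclear long noncoding RNAs KCNQ1OT1 (−1.18 ± 0.17) and NEAT1 (−1.17 ± 0.14), TIMP3, an inhibitor of matrix metalloproteinases (−1.11 ± 0.19), HLA-DMA, FAM156B, the caspase CASP2 (−1.04 ± 0.13), the actin crosslinker ACTN4 (−1.01 ± 0.14), the mitotic kinesin KIF23 (−0.95 ± 0.19) and TTLL3. Their adjusted p ran from 0.0051 for LYPLA1 to 0.037 for HLA-DMA (edgeR, Benjamini-Hochberg). H4C14 and FAM156B have near-identical copies, and KCNQ1OT1 lies antisense within KCNQ1, so their estimated counts are uncertain.

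Most genes of the matrix and of focal adhesions did not pass at 120 kPa, but the share that did exceeded that over all genes (1224 of 13990). Of 24 collagens and matrix glycoproteins 5 fell and 0 rose, and 7 fell adjusted over the list alone. The median was −0.23 on the log2 scale (camera adjusted p = 0.00038, adjusted p = 0.34 with an estimated correlation). The 5 that fell were FN1 (−0.92 ± 0.13), the proteoglycan VCAN (−0.80 ± 0.11), the laminin chains LAMA4 (−0.58) and LAMC1 (−0.60), and COL12A1. Without the block the median of this list was −0.23 (camera adjusted p = 0.018). It was −0.19 (0.081) without control replicate 1, −0.21 (0.11) without siNemp1 replicate 3 and −0.35 without control replicate 3. Among 25 matrix remodelling genes 1 rose, PLAU, and 4 fell, including TIMP3, the plasminogen activator PLAT (−0.45) and the lysyl hydroxylase PLOD1 (−0.36), with 2 and 8 adjusted over the list alone (camera adjusted p = 0.056). Of 24 focal adhesion genes 3 rose, the integrin-linked kinase ILK (0.49), FERMT2 and TES. In that list 2 fell, the focal adhesion kinase PTK2 (−0.70 ± 0.10) and TNS3, with the same numbers adjusted over the list alone and a camera adjusted p of 0.26. Among 27 contractile and SRF target genes caldesmon (CALD1, −0.45) and the myosin kinase MYLK (−0.38) fell and tropomyosin TPM1 (0.33) rose, also adjusted over the list alone. The median was −0.18 on the log2 scale (camera adjusted p = 0.040, adjusted p = 0.58 with an estimated correlation). With length and GC trends of the libraries removed, a setting added after the data were seen, it was −0.09 and the list did not pass (0.072).

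In the blocked fit at 120 kPa the mitotic and replication lists lay lower and the p53 list higher, though most of their members did not pass. Of 34 mitotic genes 6 fell and 0 rose, and 8 fell adjusted over the list alone. The median was −0.29 on the log2 scale (camera adjusted p = 3.9e-06, adjusted p = 0.58 with an estimated correlation). MKI67 (−0.84 ± 0.16), the kinetochore genes CENPF (−0.61) and CENPE (−0.61) and the spindle gene ASPM (−0.63) were among those that fell. Of 34 replication genes 4 fell, including CLSPN (−0.70), MCM4 and POLA1, and 2 rose, among them RPA2, with 5 and 2 adjusted over the list alone. The median was −0.17 on the log2 scale (camera adjusted p = 0.013, adjusted p = 0.60 with an estimated correlation). Of 27 p53 targets 7 rose and 0 fell, and 9 rose adjusted over the list alone. The median was 0.45 on the log2 scale (camera adjusted p = 3.9e-06, adjusted p = 0.52 with an estimated correlation). The 7 included TRIAP1 (0.88 ± 0.12), the death receptor FAS (0.85 ± 0.19) and the ribonucleotide reductase subunit RRM2B (0.62). The cell cycle inhibitor CDKN1A, at 535 ± 290.4 CPM in control and 753 ± 481 in siNemp1, did not pass. Without the pair of libraries numbered 3, a setting added after the data were seen, camera's adjusted p was 0.079 for the mitotic list (median −0.18), 0.71 for the replication list (−0.06) and 0.051 for the p53 list (0.25). Without the block the medians were −0.25, −0.16 and 0.57 for these lists (camera adjusted p = 0.00035, 0.022 and 0.00100). Without siNemp1 replicate 3 as well they were −0.08, −0.03 and −0.04 (0.50, 0.65 and 0.71), so the p53 median changed its sign. The mitotic median was −0.09 (0.090) without control replicate 1 and −0.49 without siNemp1 replicate 1. The replication median was −0.11 (0.069) without control replicate 1, −0.13 (0.11) without control replicate 3 and −0.30 without siNemp1 replicate 1.

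Under siNemp1 genes of translation and respiration moved apart by genome, as they also did between replicates 3 and 1 at 120 kPa. Of 27 nuclear-encoded respiratory chain genes 13 rose and 0 fell, and 21 rose adjusted over the list alone. The median was 0.37 on the log2 scale (camera adjusted p = 1.7e-10, adjusted p = 0.47 with an estimated correlation). NDUFA4 (0.69 ± 0.12), ATP5PB (0.57) and COX4I1 (0.48) were among those that rose. Of 13 mitochondrially encoded genes 11 fell and 0 rose, and 12 fell adjusted over the list alone. The median was −0.59 on the log2 scale (camera adjusted p = 2.2e-12, adjusted p = 0.47 with an estimated correlation). MT-ND4 (−0.61 ± 0.12), MT-CO3 (−0.61) and MT-ATP6 (−0.61) were examples of the fall. The mitochondrial share of the counts was 1.73%, 1.40% and 0.913% in the control and 1.06%, 0.826% and 0.709% in the siNemp1 libraries numbered 1, 2 and 3. The share from genes named as ribosomal RNA, mitochondrial ones included, fell in the same order. It was 0.394%, 0.304% and 0.229% in these control and 0.255%, 0.237% and 0.164% in these siNemp1 libraries. Of 36 cytosolic ribosomal protein genes 11 rose and 0 fell, and 21 rose adjusted over the list alone. The median was 0.32 on the log2 scale (camera adjusted p = 1.5e-10, adjusted p = 0.52 with an estimated correlation). RPS18 (0.68), RPS6 (0.60) and RPL5 (0.53) were among these. Between replicates 3 and 1, over both treatments, the ribosomal protein, respiratory chain and mitochondrially encoded lists had medians of 0.31, 0.29 and −0.69 (camera adjusted p = 1.3e-05, 0.0058 and 3.5e-10). Without the block the ribosomal protein median was 0.30, and 0.16 without control replicate 1 and 0.19 without siNemp1 replicate 3, and the mitochondrially encoded median was −0.62, and −0.40 without control replicate 1. These lists kept their calls there. Ribosomal protein genes have processed pseudogenes that can take part of their reads.

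**Figure D2:**
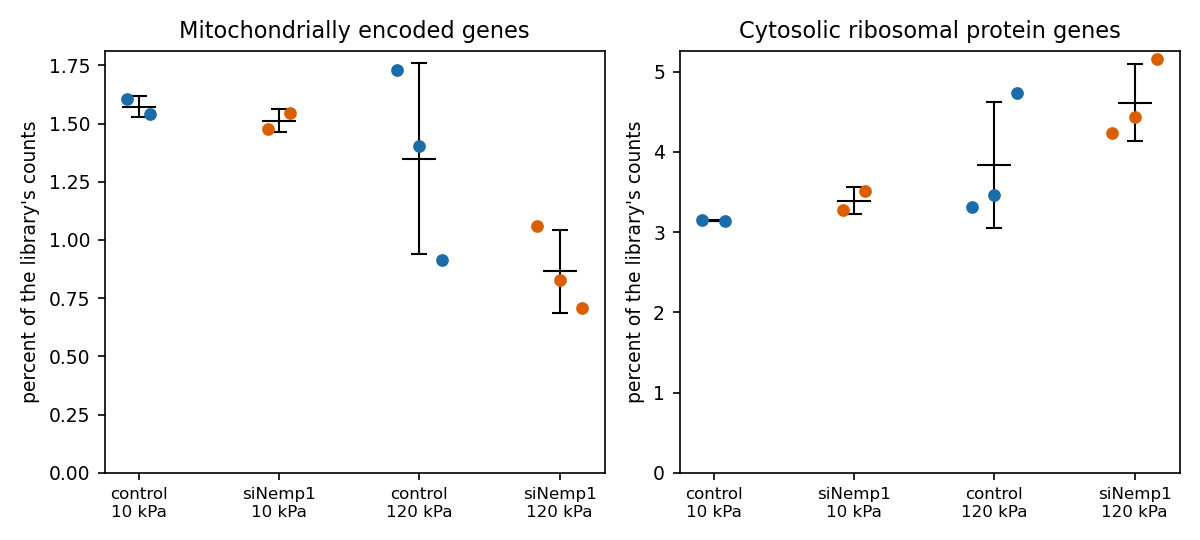
Share of each library's counts, in percent, from mitochondrially encoded genes (left) and from cytosolic ribosomal protein genes (right), 1 point per library with group mean and SD in black. The mitochondrial share is lowest, at 0.709%, and the ribosomal protein share highest, at 5.15%, in the siNemp1 library numbered 3 at 120 kPa.

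Stress, hypoxia and interferon genes moved in small numbers at 120 kPa. Of 29 unfolded protein and integrated stress response genes 3 rose, the chaperone cofactor DNAJB9 (0.83 ± 0.15) and the folate enzymes MTHFD2 and SHMT2, with 6 higher and 1 lower adjusted over the list alone. The median was 0.19 on the log2 scale (camera adjusted p = 0.024, adjusted p = 0.58 with an estimated correlation). Of 28 hypoxia and glycolysis genes PGK1 (0.68 ± 0.12), PGAM1 (0.43) and BNIP3 (0.38) rose, 4 adjusted over the list alone, with a camera adjusted p of 0.087. Of 28 interferon response genes 1 fell, the antiviral synthetase OAS3 (−0.81 ± 0.16), 1 adjusted over the list alone, and the list lay lower. The median was −0.30 on the log2 scale (camera adjusted p = 0.00029, adjusted p = 0.47 with an estimated correlation). Of 20 replication-dependent histone genes 1 rose, H4C3 (median log2 0.39, camera adjusted p = 0.040, adjusted p = 0.47 with an estimated correlation), and of 6 fibroblast markers 1 fell, THY1 (median log2 −0.29, camera adjusted p = 0.044, adjusted p = 0.58 with an estimated correlation). Without the block the contractile, stress response, histone and fibroblast lists did not pass (camera adjusted p = 0.061, 0.15, 0.064 and 0.15). With length and GC trends removed the histone list did not pass either (median 0.35, camera adjusted p = 0.062). Without the pair numbered 3 the contractile (0.20), interferon (0.060), stress response (0.073), histone (0.079) and fibroblast (0.41) lists did not, with a contractile median of −0.12 and a fibroblast median of −0.11. Without the pair numbered 1 the histone list did not pass (0.069), and the replication, interferon and fibroblast medians were −0.30, −0.47 and −0.67. Leaving out the pair numbered 2 ended no list call of the blocked fit at 120 kPa. Of 23 YAP/TAZ targets 0 rose and 2 fell, 2 and 4 adjusted over the list alone, and CCN1 (0.44 ± 0.45), CCN2 (0.47 ± 0.14) and ANKRD1 (0.31 ± 0.13) did not pass. NEMP1 was the sole gene to pass among 28 nuclear envelope and LINC genes, where SUN1 (0.17 ± 0.10), SUN2 (−0.13 ± 0.20), SYNE2 (−0.30 ± 0.16), EMD (0.32 ± 0.15), LMNA (−0.14 ± 0.35) and LMNB1 (−0.77 ± 0.29) did not. Among the 15 genes fixed for every comparison MKI67 fell and the others, with COL1A1 (−0.18 ± 0.18), ACTB (−0.18 ± 0.11) and GAPDH (−0.04 ± 0.12), did not pass. Without the block edgeR called 582 genes when the control library numbered 3 was left out, 11 without the siNemp1 library numbered 3, and 1 without the control library numbered 1 or the siNemp1 library numbered 1 or 2. With the block, in settings added after the data were seen, it called 1552, 2 and 755 without the pairs numbered 1, 2 and 3, 735 without siNemp1 replicate 3 and 1255 in the libraries at 120 kPa alone.

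**Figure D3:**
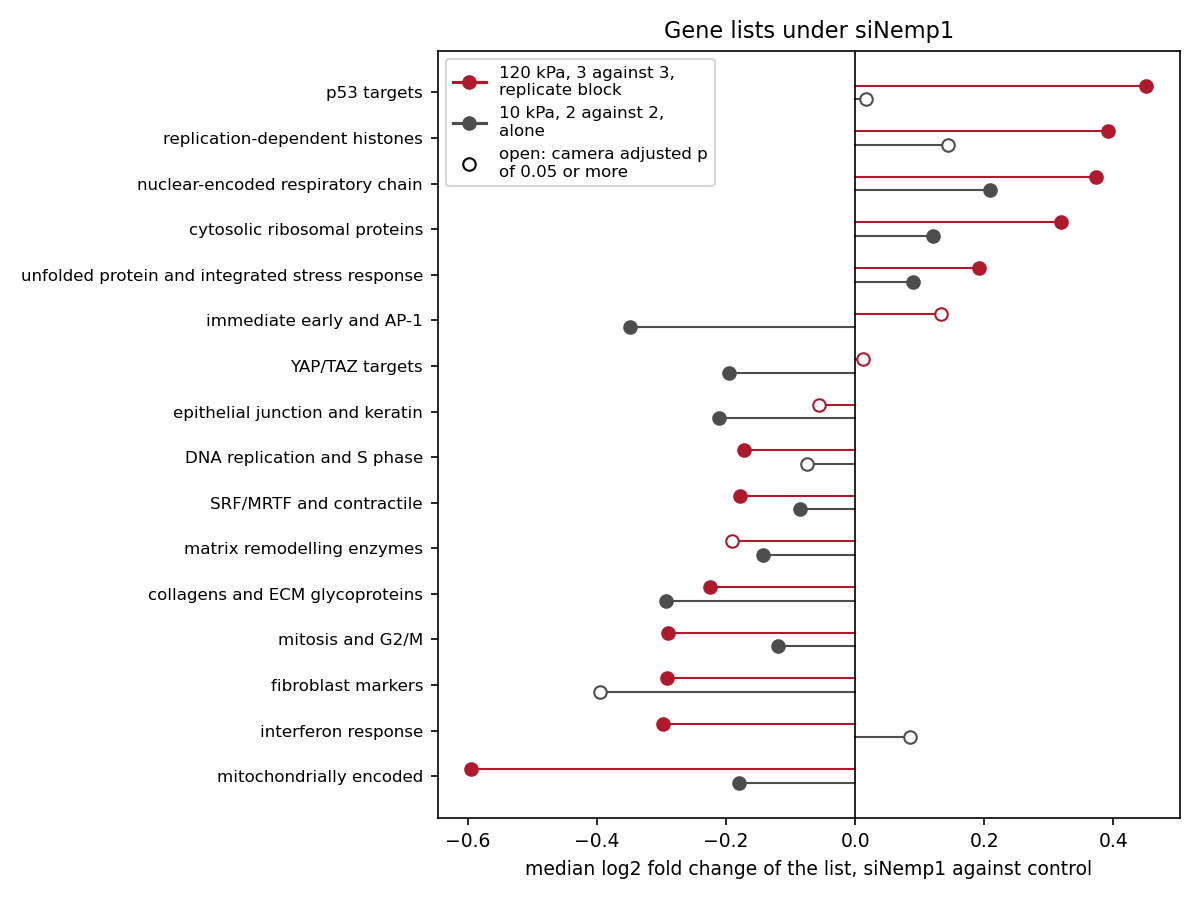
Median log2 fold change under siNemp1 of each gene list that passed camera's test at either stiffness, at 120 kPa in the blocked fit (3 against 3 libraries) and at 10 kPa in the fit of the 4 libraries there (2 against 2). Filled points have a camera adjusted p under 0.05, and mitochondrially encoded genes lie at −0.59 and −0.18.

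The same contrast was drawn on the soft substrate. AKR1B1 (chromosome 7, 134442350 to 134459284), the aldose reductase of the polyol pathway, lay at 696 ± 34.0 CPM in siNemp1 against 1739.5 ± 29.5 in control cells (mean ± SD, n = 2 each), and FN1 at 5772 ± 57.7 against 9221 ± 192. The growth-suppressive arrestin-domain gene ARRDC3 lay at 162 ± 0.305 against 89.9 ± 0.233 CPM and PGK1 at 1077 ± 52.7 against 743 ± 3.28. In the fit of all libraries without the block edgeR called 0 genes, with 850 at an unadjusted p under 0.05 and 17 called by DESeq2. With the block it called 4: AKR1B1 and GDF3 fell, and H2AC19 and INTS3 rose, the latter pair with 0 counts in most libraries and thus uncertain. Without the block the count was 2 without control replicate 1 or siNemp1 replicate 2 at 10 kPa and 1 without control replicate 3 at 120 kPa. Fitted alone, the 4 libraries gave 2308 of 13345 genes, 1081 higher and 1227 lower, of which 81 changed at least 2-fold. Their common dispersion was 0.00423, against 0.0387 over all libraries, so this count rests on how alike these 2 pairs of replicates were. The gene values of this comparison are from that fit, which was also set in advance, as an alternative to the fit of all libraries. The same kind of fit at 120 kPa called 0 genes.

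Among called genes with a mean of at least 5 CPM and no overlap between the groups, the largest falls at 10 kPa included the transporter SLCO4A1 (−1.60 ± 0.14), the immediate early gene FOS (−1.39 ± 0.20), AKR1B1 (−1.33 ± 0.06), the prostaglandin synthase PTGS2 (−1.23 ± 0.18), SERPINA1, NEMP1 (−0.99 ± 0.15), MICALL1 and TIMP3 (−0.93 ± 0.16). The largest rises were TNKS (1.33 ± 0.21), the chemokine CXCL8 (1.15 ± 0.21), H4C14, LRRC17 (0.97 ± 0.08), ZNF627, RUFY1, ARRDC3 (0.84 ± 0.06), the chemokine CXCL1, the iron exporter SLC40A1 (0.81 ± 0.13) and IQGAP2. Adjusted p in edgeR's test with Benjamini-Hochberg adjustment ran from 5.1e-13 for AKR1B1 to 0.0051 for CXCL1.

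Matrix and YAP/TAZ target genes lay lower at 10 kPa. Of 23 collagens and matrix glycoproteins 10 fell and 1 rose, 12 and 1 adjusted over the list alone (median log2 −0.29, camera adjusted p = 4.5e-08, adjusted p = 0.58 with an estimated correlation), with FN1 (−0.69 ± 0.06), VCAN (−0.56) and LAMC1 (−0.52) as examples. Of 23 YAP/TAZ targets 8 fell and 0 rose, also adjusted over the list alone. The median was −0.20 on the log2 scale (camera adjusted p = 0.0014, adjusted p = 0.58 with an estimated correlation). Those that fell included PTPN14 (−0.35), DOCK5 (−0.46) and CCDC80 (−0.36), while CCN1 (0.16 ± 0.31), CCN2 (0.24 ± 0.10) and ANKRD1 (0.18 ± 0.08) did not pass. Of 27 contractile and SRF targets 6 fell, such as MYLK (−0.42) and talin (TLN1, −0.40), and 2 rose, 8 and 2 adjusted over the list alone. The median was −0.09 on the log2 scale (camera adjusted p = 0.014, adjusted p = 0.59 with an estimated correlation). Of 24 focal adhesion genes 9 fell, among them the integrin ITGA3 (−0.52), and 2 rose, 10 and 3 adjusted over the list alone (camera adjusted p = 0.064). Of 28 nuclear envelope and LINC genes 6 fell and 2 rose, 7 and 4 adjusted over the list alone (camera adjusted p = 0.20), among the falls NEMP1, the giant nesprin SYNE2 (−0.58 ± 0.13), the linker PLEC (−0.63 ± 0.11) and LMNB1 (−0.53 ± 0.18). SUN1 (0.15 ± 0.06), SUN2 (−0.14 ± 0.14), EMD (0.00 ± 0.08) and LMNA (−0.16 ± 0.18) did not pass. The matrix remodelling list (median log2 −0.14, camera adjusted p = 0.020, adjusted p = 0.59 with an estimated correlation) lay lower, with 6 of 22 fallen and 4 risen, 8 and 4 adjusted over the list alone. The stress response list (median log2 0.09, camera adjusted p = 0.035, adjusted p = 0.59 with an estimated correlation) lay higher, with 6 of 29 risen and 3 fallen, 7 and 3 adjusted over the list alone. In the fit of all libraries without the block the collagen, immediate early, ribosomal protein, respiratory chain and epithelial lists also passed, and the YAP/TAZ (0.051), mitotic (0.063) and other lists given here did not. The fibroblast list (median −0.38, camera adjusted p = 0.046) passed in that fit and not in the fit of the 4 libraries (0.13). In that fit of all libraries, without siNemp1 replicate 2 at 10 kPa, the ribosomal protein median went from 0.13 to 0.04 (0.26), the immediate early median from −0.34 to −0.24 (0.060), and the respiratory chain median from 0.22 to 0.14 (0.036). The ribosomal protein median was 0.22 without siNemp1 replicate 1 there. The epithelial list, at 0.046, had an adjusted p of 0.054, 0.12 and 0.17 without control replicate 1, control replicate 2 and siNemp1 replicate 2 at 10 kPa, and 0.068 without control replicate 3 at 120 kPa. Its median was −0.16, and −0.05 without control replicate 1. The fibroblast list lost its call without control replicate 1 (0.45), siNemp1 replicate 1 (0.082) or siNemp1 replicate 2 (0.15) at 10 kPa, or control replicate 1 (0.062) or 3 (0.064) at 120 kPa.

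Of 34 mitotic genes 12 fell and 0 rose at 10 kPa, 14 and 0 adjusted over the list alone (median log2 −0.12, camera adjusted p = 0.00015, adjusted p = 0.58 with an estimated correlation), among them MKI67 (−0.62 ± 0.06) and CENPF (−0.60). Of 26 immediate early genes 6 fell and 0 rose, 10 and 3 adjusted over the list alone (median log2 −0.35, camera adjusted p = 0.0057, adjusted p = 0.60 with an estimated correlation), with EGR1 (−0.59) and NR4A2 (−1.34) beside FOS. Of 27 respiratory chain genes 13 rose and 0 fell, 18 and 0 adjusted over the list alone (median log2 0.21, camera adjusted p = 4.5e-08, adjusted p = 0.59 with an estimated correlation), such as CYC1 (0.41) and COX4I1 (0.36). Of 36 ribosomal protein genes 10 rose and 0 fell, 13 and 0 adjusted over the list alone (median log2 0.12, camera adjusted p = 3.5e-06, adjusted p = 0.61 with an estimated correlation), such as RPLP0 (0.36) and RPS6 (0.23). Of 13 mitochondrially encoded genes 6 fell, such as MT-CO3 (−0.24), and 1 rose, MT-CO1 (0.39), with 6 and 1 adjusted over the list alone. The median was −0.18 on the log2 scale (camera adjusted p = 0.045, adjusted p = 0.63 with an estimated correlation). Of 13 epithelial junction and keratin genes 5 fell, the desmosomal genes DSP (−0.52) and JUP (−0.36) among them, and 1 rose, 5 and 1 adjusted over the list alone. The median was −0.21 on the log2 scale (camera adjusted p = 0.025, adjusted p = 0.61 with an estimated correlation).

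Averaging the knockdown effect over both stiffnesses used all 5 control and 5 siNemp1 libraries. PLAU (0.98 ± 0.20), ZNF627 (0.94 ± 0.15), ARRDC3 (0.84 ± 0.12), SLC40A1 (0.79 ± 0.15), the tubulin TUBA1A (0.70 ± 0.14), the ephrin ligand EFNA1 (0.68 ± 0.13), C5orf15, the lysosomal thioesterase PPT1 (0.63 ± 0.09), FAM118B and CLDND1 had the largest rises without the block. NEMP1 (−1.16 ± 0.18), KCNQ1OT1 (−0.94 ± 0.13), PTGS2 (−0.79 ± 0.13), ACTN4 (−0.71 ± 0.14), ZFHX3 (−0.69 ± 0.12), the endocytic scaffold ITSN1 (−0.68 ± 0.09), NEAT1 (−0.66 ± 0.12), OAS3, the ciliary gene CEP164 and UNC13A had the largest falls. LAMC1 (−0.55 ± 0.11) and CENPF (−0.60 ± 0.12) fell from the matrix and mitotic lists. edgeR called 180 genes, 120 higher and 60 lower, with adjusted p no lower than 0.0442 (Benjamini-Hochberg), and with the replicate block 1504, 921 higher and 583 lower, which hold all 180. With the block, FN1 (−0.80 ± 0.10), VCAN (−0.67 ± 0.09) and TIMP3 (−1.01 ± 0.14) were among the falls.

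Across both stiffnesses 14 of 27 respiratory chain genes rose and 0 fell in the blocked fit, 21 and 0 adjusted over the list alone (median log2 0.31, camera adjusted p = 8e-10, adjusted p = 0.57 with an estimated correlation), as did 10 of 36 ribosomal protein genes, 15 adjusted over the list alone (median log2 0.23, camera adjusted p = 7.5e-09, adjusted p = 0.57 with an estimated correlation). Of 24 collagens and matrix glycoproteins 7 fell and 0 rose, 8 and 0 adjusted over the list alone. The median was −0.19 on the log2 scale (camera adjusted p = 8.9e-06, adjusted p = 0.16 with an estimated correlation). Of 34 mitotic genes 7 fell and 0 rose, 7 and 0 adjusted over the list alone. The median was −0.19 on the log2 scale (camera adjusted p = 2.8e-05, adjusted p = 0.57 with an estimated correlation). Of 13 mitochondrially encoded genes 4 fell, 11 adjusted over the list alone. The median was −0.33 on the log2 scale (camera adjusted p = 3.3e-07, adjusted p = 0.57 with an estimated correlation). Of p53 targets 4 rose and 0 fell, 7 and 0 adjusted over the list alone (median log2 0.26, camera adjusted p = 0.00095, adjusted p = 0.57 with an estimated correlation). Of stress response genes 2 rose and 0 fell, 5 and 0 adjusted over the list alone (median log2 0.17, camera adjusted p = 0.028, adjusted p = 0.57 with an estimated correlation). Of contractile and SRF targets 1 rose and 4 fell, 2 and 4 adjusted over the list alone (median log2 −0.13, camera adjusted p = 0.030, adjusted p = 0.57 with an estimated correlation). Of matrix remodelling genes 2 rose and 3 fell, 2 and 7 adjusted over the list alone (median log2 −0.14, camera adjusted p = 0.028, adjusted p = 0.57 with an estimated correlation). Of replication genes 1 rose and 3 fell, 1 and 4 adjusted over the list alone (median log2 −0.11, camera adjusted p = 0.030, adjusted p = 0.61 with an estimated correlation). In the fit without the block the camera adjusted p of these 5 lists were 0.026, 0.097, 0.054, 0.068 and 0.054. The p53 median was then 0.30, and at 120 kPa 0.21 (0.084) without control replicate 1, 0.45 without control replicate 3 and 0.00065 (0.39) without siNemp1 replicate 3. In the blocked fit without the pair numbered 3 at 120 kPa the p53 (median 0.14, camera adjusted p = 0.076), contractile (0.10), remodelling (0.056) and replication (median −0.05, 0.34) lists did not pass. Without the pair numbered 1 the remodelling and replication medians were −0.22 and −0.16. Without the block the mitotic median was −0.17, and at 120 kPa −0.10 (camera adjusted p = 0.13) without siNemp1 replicate 3, −0.10 without control replicate 1 and −0.31 without siNemp1 replicate 1. The ribosomal protein median went from 0.23 to 0.15 without control replicate 1 at 120 kPa, and the collagen median from −0.18 to −0.28 without siNemp1 replicate 2 at 10 kPa. In the fit without the block the count of called genes was 0 without control replicate 2 or siNemp1 replicate 1 at either stiffness. It was 2 without control replicate 1 or siNemp1 replicate 2 at 10 kPa, 1 without siNemp1 replicate 2 at 120 kPa, and 369, 666 and 334 without control replicate 1, control replicate 3 and siNemp1 replicate 3 at 120 kPa. It was 0 with DESeq2's size factors and 71, 35 higher and 36 lower, with upper-quartile scaling, which in the blocked fit called 1454, 738 higher and 716 lower.

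The knockdown effects on both substrates were then compared gene by gene. Of the 873 genes that rose at 120 kPa in the blocked fit, 838 also lay higher at 10 kPa, with a median log2 change of 0.26 there against 0.52 at 120 kPa. Of the 351 that fell, 335 lay lower at 10 kPa, with medians of −0.29 and −0.52. Among 13345 genes tested in both fits, 438 rose at 120 kPa in the blocked fit and at 10 kPa alone, where independent lists of 865 and 1081 genes would share 70.1. The falls shared 230 genes, where lists of 346 and 1227 would share 31.8. Across all 13990 genes, which are not independent replicates, the fold changes at both stiffnesses had a Spearman correlation of 0.453 and a Pearson correlation of 0.165, and 0.663 and 0.525 over the 9651 genes with a mean of at least 5 CPM. The groups compared at each stiffness share no library, but the blocked fit takes its block and dispersions from all 10 libraries. In fits of the libraries at each stiffness alone, with the block at 120 kPa, which share none, a setting added after the data were seen, 427 genes rose in both and 272 fell in both of 13122 tested. Independent lists of 1077 and 795 genes would share 65.3 rises, and lists of 1208 and 455 would share 41.9 falls.

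The difference between the knockdown effects tests whether the response to siNemp1 depends on stiffness. AKR1B1 lay at 1739.5 ± 29.5 CPM in control cells at 10 kPa, and at 696 ± 34.0, 844 ± 175 and 823 ± 91.3 in siNemp1 cells at 10 kPa and in control and siNemp1 cells at 120 kPa, which gave a difference between the knockdown effects that passed (log2 1.30 ± 0.15, adjusted p = 0.0075 by edgeR with the block). GATAD2B, a subunit of a chromatin remodelling complex, lay at 3.82 and 4.37 CPM in control at 10 kPa, at 0.0453 to 0.11 in control at 120 kPa, and between 0.713 and 2.74 in siNemp1 libraries (difference 6.92 ± 0.73, adjusted p = 0.021 by edgeR without the block). The control libraries at 120 kPa held a few counts of it at most, so the fitted size and its SE depend on the prior count. edgeR called 1 gene without the block, GATAD2B, with 235 at an unadjusted p under 0.05 and 3 called by DESeq2. With the block it called 4, AKR1B1, GATAD2B, H2AC19 and the readthrough gene BLOC1S5-TXNDC5, the last pair with 0 counts in most libraries. GATAD2B and H2AC19 were chosen for naming after their values were seen. The count without the block was 3 without control replicate 1 or siNemp1 replicate 2 at 10 kPa, 2 without control replicate 1 or siNemp1 replicate 2 at 120 kPa, and 1 without siNemp1 replicate 1 at 120 kPa. It was 0 without control replicate 2 or siNemp1 replicate 1 at 10 kPa, or control replicate 2 or 3 or siNemp1 replicate 3 at 120 kPa. GATAD2B lost its call in these 5 settings and without siNemp1 replicate 2 at 10 kPa (adjusted p = 0.064), where the 3 called genes were others. Other genes called at 1 stiffness are therefore not shown to differ from the other stiffness.

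The lists gave a further view of this difference, without the block. Immediate early genes lay higher in the difference (median log2 0.38, camera adjusted p = 0.00029, adjusted p = 0.90 with an estimated correlation), with FOS at 8.48 ± 0.667 CPM in control and 3.24 ± 0.580 in siNemp1 cells at 10 kPa, against 3.06 ± 0.176 and 3.59 ± 0.467 at 120 kPa. The p53 targets (median log2 0.47, camera adjusted p = 0.0052, adjusted p = 0.90 with an estimated correlation) also lay higher. So did ribosomal protein genes (median log2 0.16, camera adjusted p = 0.014, adjusted p = 0.90 with an estimated correlation). Mitochondrially encoded genes (median log2 −0.46, camera adjusted p = 4.1e-07, adjusted p = 0.90 with an estimated correlation) lay lower. Interferon response genes did as well (median log2 −0.29, camera adjusted p = 2.8e-07, adjusted p = 0.57 with an estimated correlation), with IFIT3, an interferon-induced antiviral gene, at 48.9 ± 2.40 and 63.7 ± 1.35 CPM at 10 kPa and 70.2 ± 11.8 and 54.7 ± 7.31 at 120 kPa. No member of these 5 lists passed over all genes, and adjusted over the list alone 1 immediate early gene rose and 0 others did. In the blocked fit the mitotic list also passed (median −0.07, camera adjusted p = 0.010, adjusted p = 0.89 with an estimated correlation). So did the respiratory chain list (median 0.14, camera adjusted p = 0.0083, adjusted p = 0.89 with an estimated correlation). Leaving out pairs at 120 kPa moved the lists of the blocked fit. The mitotic median was −0.21, −0.14 and −0.03 (0.95) without the pairs numbered 1, 2 and 3, and the respiratory chain median 0.09 (0.50) without the pair numbered 1 and 0.21 without the pair numbered 3. The ribosomal protein median, 0.18 with the block, was 0.08 (0.052) and 0.15 (0.072) without the pairs numbered 1 and 2. The p53 median, 0.32 with the block, was 0.48 and 0.12 (0.15) without the pairs numbered 2 and 3. The interferon median went from −0.32 to −0.51 without the pair numbered 1, and the immediate early median from 0.37 to 0.23 without the pair numbered 3. Of the 15 genes fixed in every comparison 0 passed in either fit, with log2 differences from −0.28 to 0.56 without the block and −0.32 to 0.48 with it. Medians without the block moved when 1 library was left out, given here with the camera adjusted p where the call ended. At 120 kPa the p53 median was 0.27 (0.16) without control replicate 1, 0.74 without control replicate 3 and −0.05 (0.59) without siNemp1 replicate 3. The immediate early median was 0.11 (0.14), 0.72 and −0.0047 (0.15) without these 3 libraries, 0.71 without siNemp1 replicate 1 and 0.23 without siNemp1 replicate 2 at 10 kPa. The ribosomal protein median was 0.05 (0.65), 0.07 (0.40) and 0.30 without control replicate 1, 2 and 3, and 0.07 (0.25) without siNemp1 replicate 3, at 120 kPa. At 10 kPa it was 0.15 (0.090) without control replicate 1 and 0.07 (0.67) without siNemp1 replicate 1. The mitochondrially encoded median was −0.25 without control replicate 1 and the interferon median −0.50 without siNemp1 replicate 1, both at 120 kPa.

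In control cells, the stiff and the soft substrate differed in few single genes. GDF3, a ligand of the TGF-beta family, lay at 5.11 and 4.80 CPM in the control libraries at 10 kPa and at no more than 0.0453 in any other library, and GATAD2B fell from 3.82 and 4.37 to between 0.0453 and 0.11 CPM. AKR1B1, set apart by the same group as above, had a log2 change of −1.19 ± 0.11 in the blocked fit (adjusted p = 0.0020, edgeR with Benjamini-Hochberg adjustment). edgeR called 2 genes without the block, GATAD2B and GDF3, and 3 with it, AKR1B1 being added. Without the block 569 had an unadjusted p under 0.05, and DESeq2 called 12. The count was 0 without control replicate 2 at 10 kPa or without control replicate 1, 2 or 3 at 120 kPa. GATAD2B and GDF3 have a mean under 5 CPM and were chosen for naming after their values were seen. None of the 15 fixed genes passed, with log2 changes from −0.39 to 0.66: CCN1 (0.66 ± 0.62), CCN2 (0.29 ± 0.30), ANKRD1 (0.44 ± 0.35), LMNA (0.07 ± 0.34) and COL1A1 (0.30 ± 0.27) were among them, the first 3 being targets of the mechanosensitive coactivators YAP and TAZ.

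Between substrates, gene lists passed camera's test in control cells where their single members did not. Ribosomal protein genes (median log2 0.27, camera adjusted p = 6.5e-14, adjusted p = 0.46 with an estimated correlation) lay higher at 120 kPa. Respiratory chain genes (median log2 0.30, camera adjusted p = 1.4e-09, adjusted p = 0.46 with an estimated correlation) did too, and examples of both are RPSA (0.69 ± 0.28) and ATP5PO (0.59 ± 0.24). Interferon response genes (median log2 0.21, camera adjusted p = 1.2e-05, adjusted p = 0.46 with an estimated correlation) also lay higher, with the antiviral gene OAS1 (0.45 ± 0.14) as an example. NF-kB and cytokine genes (median log2 0.40, camera adjusted p = 0.00024, adjusted p = 0.58 with an estimated correlation) did so too, with CXCL1 (1.37 ± 0.48) as an example. Stress response genes (median log2 0.31, camera adjusted p = 0.00024, adjusted p = 0.46 with an estimated correlation) were also higher, for example the asparagine synthetase ASNS (1.37 ± 0.73). YAP/TAZ targets (median log2 −0.22, camera adjusted p = 0.011, adjusted p = 0.46 with an estimated correlation) lay lower. Collagens and matrix glycoproteins (median log2 −0.20, camera adjusted p = 0.011, adjusted p = 0.46 with an estimated correlation) and mitotic genes (median log2 −0.17, camera adjusted p = 0.0079, adjusted p = 0.61 with an estimated correlation) lay lower without the block. So did mitochondrially encoded genes (median log2 −0.16, camera adjusted p = 0.011, adjusted p = 0.60 with an estimated correlation), while p53 targets lay higher (median log2 0.29, camera adjusted p = 0.0072, adjusted p = 0.60 with an estimated correlation). With the block the camera adjusted p of these 4 lists were 0.090, 0.71, 0.71 and 0.80, with a mitotic median of 0.0020 and a p53 median of −0.04. The immediate early list then passed (median −0.21, camera adjusted p = 4.5e-05, adjusted p = 0.78 with an estimated correlation). Between stiffnesses the block takes up the level of replicate 3, present at 120 kPa only, so these values rest mainly on replicates 1 and 2. The mesenchymal and epithelial transition factors (median log2 −0.15, camera adjusted p = 0.015, adjusted p = 0.46 with an estimated correlation) and the 6 fibroblast markers (median log2 −0.15, camera adjusted p = 0.015, adjusted p = 0.58 with an estimated correlation) also lay lower without the block. With it neither passed (camera adjusted p = 0.14 and 0.80), and the fibroblast median was 0.14. No member of these lists passed over all genes. Adjusted over the list alone and without the block 1 NF-kB gene, PTGS2, and 1 fibroblast marker fell, and 0 rose. With the block 2 immediate early genes, 1 YAP/TAZ target, 1 NF-kB gene and 1 fibroblast marker fell, and 1 NF-kB gene rose. Without control replicate 3 at 120 kPa the adjusted p was 0.11 for collagens, 0.12 for mitosis, 0.30 for p53 targets and 0.088 for NF-kB genes, and the mitochondrially encoded median was 0.04. The medians of mitosis, p53 targets and NF-kB genes were then −0.07, 0.07 and 0.21, and those of YAP/TAZ targets, stress response, ribosomal protein and respiratory chain genes −0.14, 0.17, 0.13 and 0.15. Without control replicate 2 at 120 kPa the adjusted p of mitosis was 0.13, and without control replicate 1 at 10 kPa that of mitochondrially encoded genes was 0.056. Without control replicate 1 at 120 kPa the mitotic, NF-kB, stress response and mitochondrially encoded medians were −0.27, 0.65, 0.51 and −0.38. The transition factor list lost its call without control replicate 1 at 10 kPa (0.077) or control replicate 3 at 120 kPa (0.11). The fibroblast median was −0.10 (0.42) without control replicate 1 at 10 kPa, and −0.27 (0.060) and −0.01 (0.12) without control replicate 1 and 3 at 120 kPa.

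In siNemp1 cells no single gene passed between substrates without the block. The mitochondrially encoded MT-CO1 lay at 4295 ± 139 CPM at 10 kPa and 1716 ± 919.8 at 120 kPa (mean ± SD, n = 2 and 3), and the ribosomal protein gene RPS6 at 992 ± 44.0 and 1811 ± 61.6. FAS lay at 22.8 ± 1.46 and 51.2 ± 32.7 CPM and MTHFD2 at 66.8 ± 0.163 and 135 ± 71.6. Without the block edgeR called 0 genes, with a lowest adjusted p of 0.315, 1655 genes at an unadjusted p under 0.05 and 98 called by DESeq2. With the block it called 2, BLOC1S5-TXNDC5 and H2AC19, both lower at 120 kPa and both with 0 counts in all siNemp1 libraries there and in 1 of 2 at 10 kPa. The count was 2 without siNemp1 replicate 2 at 10 kPa and 1 without control replicate 1 or siNemp1 replicate 2 at 120 kPa. None of the 15 fixed genes passed, with log2 changes from −0.49 ± 0.22 for MKI67 to 1.13 ± 0.57 for CDKN1A.

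Ribosomal protein genes lay higher at 120 kPa in siNemp1 cells (median log2 0.43, camera adjusted p = 1.6e-16, adjusted p = 0.58 with an estimated correlation), of which 20 of 36 rose adjusted over the list alone. In the respiratory chain (median log2 0.42, camera adjusted p = 2e-11, adjusted p = 0.58 with an estimated correlation) 9 of 27 did. Of 13 mitochondrially encoded genes 11 fell adjusted over the list alone and 0 over all genes. The median was −0.63 on the log2 scale (camera adjusted p = 7.6e-12, adjusted p = 0.58 with an estimated correlation). The p53 targets (median log2 0.82, camera adjusted p = 1.1e-06, adjusted p = 0.60 with an estimated correlation) and NF-kB genes (median log2 0.53, camera adjusted p = 0.0021, adjusted p = 0.64 with an estimated correlation) lay higher. Stress response genes (median log2 0.44, camera adjusted p = 0.0036, adjusted p = 0.58 with an estimated correlation) and replication-dependent histones (median log2 0.56, camera adjusted p = 0.017, adjusted p = 0.58 with an estimated correlation) were higher as well. Mitotic genes (median log2 −0.27, camera adjusted p = 5.9e-05, adjusted p = 0.64 with an estimated correlation) and replication genes (median log2 −0.15, camera adjusted p = 0.024, adjusted p = 0.64 with an estimated correlation) lay lower. Markers of retinal pigment epithelium also lay lower (median log2 −0.26, camera adjusted p = 0.011, adjusted p = 0.58 with an estimated correlation). So did transition factors (median log2 −0.18, camera adjusted p = 0.024, adjusted p = 0.58 with an estimated correlation), which did not pass with the block (0.055), without siNemp1 replicate 1 at 10 kPa (0.090) or without siNemp1 replicate 3 at 120 kPa (0.15). Without siNemp1 replicate 3 at 120 kPa the adjusted p was 0.74 for replication, 0.25 for mitosis, 0.088 for NF-kB and 0.17 for histones, with medians of −0.07, −0.14, 0.20 and 0.26. The p53, stress response and pigment epithelium medians were then 0.19, 0.23 and −0.16. Without siNemp1 replicate 1 there the replication, mitotic and pigment epithelium medians were −0.28, −0.53 and −0.47. The adjusted p was 0.051 for replication without control replicate 3 at 120 kPa and 0.052 for histones without siNemp1 replicate 2 at 10 kPa, and with the replicate block it was 0.11 for replication.

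The average over both treatments set 6 libraries at 120 kPa against 4 at 10 kPa. NDUFA9, a complex I subunit, had a log2 change of 0.48 ± 0.10 and RPL5 of 0.54 ± 0.12, the chaperone cofactor DNAJB9 of 0.76 ± 0.17, the chemokine CXCL1 of 1.22 ± 0.33 and the transcription factor SNAI1 of −0.53 ± 0.14, none of which passed over all genes. edgeR called 0 genes without the block and 0 with it, with 2200 at an unadjusted p under 0.05 without the block and a lowest adjusted p of 0.172, and DESeq2 called 497, 459 higher and 38 lower. The count was 330 without control replicate 1 at 120 kPa, 2 without control replicate 1 or siNemp1 replicate 2 at 10 kPa and 1 without siNemp1 replicate 2 at 120 kPa. Adjusted over the list alone, 23 of 36 ribosomal protein genes rose (median log2 0.37, camera adjusted p = 5.1e-20, adjusted p = 0.43 with an estimated correlation). In the same way 16 of 27 respiratory chain genes rose (median log2 0.38, camera adjusted p = 1.4e-13, adjusted p = 0.43 with an estimated correlation), as did 6 of 24 NF-kB genes (median log2 0.53, camera adjusted p = 7e-05, adjusted p = 0.55 with an estimated correlation). Of the mitochondrially encoded genes 11 of 13 fell (median log2 −0.40, camera adjusted p = 7.5e-09, adjusted p = 0.43 with an estimated correlation). In these lists 0 members passed over all genes. The p53 targets (median log2 0.50, camera adjusted p = 4.4e-06, adjusted p = 0.55 with an estimated correlation) lay higher and mitotic genes (median log2 −0.24, camera adjusted p = 6.1e-05, adjusted p = 0.55 with an estimated correlation) lower, with 0 members passing over all genes or over the list alone. Without siNemp1 replicate 3 at 120 kPa the NF-kB, p53 and mitotic medians were 0.31, 0.25 and −0.14. Stress response genes (median log2 0.41, camera adjusted p = 0.00012, adjusted p = 0.43 with an estimated correlation) and replication-dependent histones (median log2 0.40, camera adjusted p = 0.011, adjusted p = 0.45 with an estimated correlation) lay higher. Collagens and matrix glycoproteins (median log2 −0.14, camera adjusted p = 0.018, adjusted p = 0.43 with an estimated correlation) and replication genes (median log2 −0.17, camera adjusted p = 0.039, adjusted p = 0.62 with an estimated correlation) lay lower. Transition factors (median log2 −0.14, camera adjusted p = 0.0073, adjusted p = 0.43 with an estimated correlation) and pigment epithelium markers (median log2 −0.25, camera adjusted p = 0.011, adjusted p = 0.43 with an estimated correlation) did too. With the block the camera adjusted p of these 6 lists were 5.1e-05, 0.078, 0.064, 0.31, 0.029 and 0.078. The YAP/TAZ list then passed (median log2 −0.13, camera adjusted p = 0.018, adjusted p = 0.59 with an estimated correlation). The blocked average rests on replicates 1 and 2, since the block takes up the mean level of replicate 3. Without siNemp1 replicate 3 at 120 kPa the stress response, histone, collagen, replication and pigment epithelium medians were 0.25, 0.21, −0.09, −0.09 and −0.15. Without control replicate 3 there the stress response and histone medians were 0.27 and 0.25, and without control replicate 1 the transition factor median was −0.22. The replication list did not pass without siNemp1 replicate 3 (0.33), control replicate 1 (0.051) or control replicate 2 (0.11) at 120 kPa, or control replicate 2 at 10 kPa (0.069). The NF-kB gene CXCL8, a neutrophil chemokine, varied within both groups at 120 kPa, at 7.22, 37.9 and 107 CPM in control and 12.7, 93.0 and 161 in siNemp1 replicates 1, 2 and 3.

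The stiffness responses of control and siNemp1 cells had a Pearson correlation of 0.143 and a Spearman correlation of 0.445 across the 13990 genes, which are not independent replicates, with 69.5% of genes differing in the same direction. Over the genes with a mean of at least 5 CPM these were 0.594, 0.652 and 75.1%. Of the covariance between both sets of fold changes, 0.0244 of 0.0429 over all genes and 0.0205 of 0.0509 over those of at least 5 CPM came from replicates at 120 kPa that share a number, which are differences between libraries and not between stiffnesses.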

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

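The test of whether fewer mitochondria account for the fall in mitochondrial transcripts was chosen after the result was seen. These 6 results passed the test of the difference between stiffnesses in the fit without the block. The 5 lists among them did so only at the preset correlation between genes, since with an estimated correlation their adjusted p was 0.57 for interferon response genes and 0.90 for the others. GATAD2B had a difference of knockdown effects of 6.92 on the log2 scale, with at most a few counts in each control library at 120 kPa. It lost its call, and edgeR called 0 genes, without control replicate 2 or siNemp1 replicate 1 at 10 kPa, or control replicate 2 or 3 or siNemp1 replicate 3 at 120 kPa. It also lost it without siNemp1 replicate 2 at 10 kPa (adjusted p = 0.064), where 3 other genes were called. The p53 target list had a median difference of 0.47, which was −0.05 without siNemp1 replicate 3 at 120 kPa and lost its call without control replicate 1 there (camera adjusted p = 0.16). The interferon response list had a median difference of −0.29, which was −0.50 without siNemp1 replicate 1 at 120 kPa. The immediate early list had a median difference of 0.38. It was −0.0047 (0.15) without siNemp1 replicate 3 and 0.11 (0.14) without control replicate 1 at 120 kPa. Leaving out a single library there parts a same-numbered pair. Medians that moved in the blocked fit with whole pairs left out are given with the lists of this difference above. The ribosomal protein list had a median difference of 0.16. It was 0.05, 0.07 and 0.07 without control replicate 1, control replicate 2 and siNemp1 replicate 3 at 120 kPa and 0.15 and 0.07 without control and siNemp1 replicate 1 at 10 kPa, and passed in none of these 5 settings.

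The mitochondrially encoded list had a median difference of −0.46, which was −0.25 without control replicate 1 at 120 kPa, with a median log2 change under siNemp1 of −0.59 at 120 kPa in the blocked fit. A single pair of libraries did not account for the fall at 120 kPa, since the median nearest to 0 with a pair left out was −0.550. A trend with the median length and GC content of annotated transcripts did not either, since the list's median was −0.665 with that trend removed. A lower content of all respiratory chain transcripts is argued against by the nuclear-encoded list, whose median was 0.374. Nuclear transcripts do not measure the number of mitochondria, so whether fewer mitochondria account for the fall stays open. The share of ribosomal RNA genes, which overlaps the mitochondrial share, was also lower in siNemp1 in each same-numbered pair. Its link to this fall was not tested. A change in mitochondrial transcription or RNA stability under siNemp1 may underlie the pattern but was not tested, and a difference in cell state between cultures stays open.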

How the results depend on the processing

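Counts of called genes moved most, and the cause was not tested except where fewer genes or libraries were fitted. With DESeq2 they were 642, 17, 12, 98, 3, 967 and 497 for siNemp1 at 120 kPa, siNemp1 at 10 kPa, stiffness in control, stiffness in siNemp1, the difference, the average knockdown and the average stiffness effect. DESeq2 tested 23537 genes with its own filter, and on the genes of the edgeR fit, a setting added after seeing the data, it gave 723, 22, 12, 106, 4, 1076 and 532 in this order. The difference between the tests thus does not come from the genes tested alone. In the same order they were 643, 66, 159, 529, 70, 649 and 839 without a filter on low counts. With 5 CPM in 2 libraries they were 119 for siNemp1 at 120 kPa, 314 for the average knockdown and 0 for stiffness in control and for the difference. The average knockdown gave 0 with DESeq2's size factors, 71 with upper-quartile scaling and 6 at a log2 change of at least 1. With only the 2 groups compared, siNemp1 at 120 kPa gave 0, siNemp1 at 10 kPa 2308, stiffness in control 3 and stiffness in siNemp1 1. With the replicate block, siNemp1 at 120 kPa gave 1224, siNemp1 at 10 kPa 4, stiffness in siNemp1 2, the difference 4 and the average knockdown 1504, and in the stiffness response of control cells the p53 list turned to −0.039, the mitotic list to 0.0020, the immediate early list to −0.21 and the fibroblast list to 0.14. The block changed no count of calls by over 1.5 times beyond these, and list calls that it changed are given where that list is reported.

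Other settings were chosen after seeing the data, and are given for siNemp1 at 120 kPa, siNemp1 at 10 kPa, the difference and the average knockdown. The block at 120 kPa only gave 2854, 61, 2 and 3215. The block with length and GC offsets gave 1671, 5, 4 and 1893, and the offsets without the block gave 131 for siNemp1 at 120 kPa and 464 for the average. The block without the pairs numbered 1, 2 and 3 gave 1552, 48, 8 and 2493, then 2, 1, 3 and 600, then 755, 5, 4 and 1592. The block without siNemp1 replicate 3 at 120 kPa gave 735, 6, 4 and 1572. The block gave 1103, 4, 4 and 1481 with DESeq2's size factors and 1215, 4, 4 and 1454 with upper-quartile scaling, and 1255 for siNemp1 at 120 kPa in the libraries there alone. Without the pair numbered 1 the fibroblast list in the difference turned to −0.51, and without the pair numbered 3 the YAP/TAZ list in the average knockdown to −0.10.

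With each library left out in turn the counts ranged from 0 to 582 for siNemp1 at 120 kPa, 0 to 2 for siNemp1 at 10 kPa, 0 to 3 for stiffness in control, 0 to 2 for stiffness in siNemp1, 0 to 3 for the difference, 0 to 666 for the average knockdown and 0 to 330 for the average stiffness effect. A group at 10 kPa then holds 1 library, which is assumed to vary like the other groups. The mitochondrially encoded list in the stiffness response of control cells ranged from −0.38 to 0.037, turning without control replicate 3 at 120 kPa, and the p53 list in the difference from −0.049 to 0.74, turning without siNemp1 replicate 3 there. Without that library the immediate early list in the difference, from −0.0047 to 0.72, and the p53 list for siNemp1 at 120 kPa, from −0.037 to 0.83, turned too. In the stiffness response of control cells the immediate early list ranged from −0.20 to 0.15, turning without control replicate 2 at 10 kPa or 3 at 120 kPa. In that of siNemp1 cells the interferon list ranged from −0.16 to 0.090, turning without siNemp1 replicate 1 at 120 kPa. The rank correlations between knockdown effects and between stiffness responses were 0.663 and 0.652 over genes of at least 5 CPM. Named genes kept their direction in all settings where they had been called.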

Other observations

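The comparison of replicates and the test of a shared batch across stiffnesses were chosen after the result was seen. At 120 kPa the libraries numbered 3 differed from those numbered 1 in both treatments, beyond any effect of siNemp1. Over both treatments 3013 genes were called between these numbers (edgeR quasi-likelihood, Benjamini-Hochberg), 1695 higher and 1318 lower in replicate 3. Of 24 NF-kB and cytokine genes 18 rose and 0 fell (median log2 1.40, camera adjusted p = 1.6e-18, adjusted p = 0.17 with an estimated correlation), with the chemokines CXCL8 (3.79) and CXCL3 (3.69) and the cytokine IL1B (3.22) as examples. Of 29 stress response genes 17 rose and 4 fell (median 0.66, camera adjusted p = 6.7e-18, adjusted p = 0.17 with an estimated correlation), among them ATF3 (3.95), CHAC1 (3.36) and TRIB3 (3.24), which the integrated stress response induces. The amino acid transporter SLC7A5 (2.89) and the transsulfuration enzyme CBS (2.90) rose as well.

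Of 27 p53 targets 18 rose and 0 fell in replicate 3 (median 1.05, camera adjusted p = 3.6e-15, adjusted p = 0.40 with an estimated correlation), among them FDXR (2.33) and GADD45A (2.28). Of 34 mitotic genes 21 fell and 0 rose (median −0.57, camera adjusted p = 2.8e-11, adjusted p = 0.49 with an estimated correlation), and of 13 mitochondrially encoded genes 12 fell (median −0.69, camera adjusted p = 3.5e-10, adjusted p = 0.40 with an estimated correlation), such as MT-CO1 (−1.37). Of 36 ribosomal protein genes 13 rose and 0 fell (median 0.31, camera adjusted p = 1.3e-05, adjusted p = 0.67 with an estimated correlation), and of 27 respiratory chain genes 7 rose and 0 fell (median 0.29, camera adjusted p = 0.0058, adjusted p = 0.67 with an estimated correlation). The alarmin IL33 (−1.33) and the growth factor receptor PDGFRA (−1.29) were also lower in replicate 3. The lists that move between replicates at 120 kPa thus include several that move with siNemp1 and with stiffness.

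Libraries with the same number deviated together at 120 kPa. A trend with the median length and GC content of annotated transcripts is not the whole of it. The lowest of the 3 correlations was 0.105 with that trend removed, close to the 0.1 that the rule for pairing asks for. It was 0.157 without the 100 most abundant of 13990 genes, but as all weigh alike this does not decide on a few abundant genes. A day or batch that the number names at both stiffnesses stays open. Correlations between stiffnesses, with a mean of −0.0461, cannot decide on it, since replicates differed far less at 10 kPa. A culture or preparation shared by each pair at 120 kPa stays open, and no biological explanation was tested.

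Under siNemp1 at 120 kPa ribosomal protein and respiratory chain genes, which are short, rose. Length slopes of the libraries were lower in siNemp1 by 0.0513 at 120 kPa, which restates this pattern on the same libraries, and by 0.0452 at 10 kPa. An exact permutation within both stiffnesses gave p = 0.0167 (two-sided, 120 permutations) but leans on that restated part, and the 6 permutations at 10 kPa alone cannot give less than the 0.333 found there. Whether a length gradient goes with siNemp1 thus stays open. Length here is the median over a gene's annotated transcripts, so a trend with the length of the transcripts expressed cannot be excluded. A trend with this median length and GC content does not account for the whole pattern. Of the 1224 genes called in the blocked fit, 1116 stayed called in the same direction with that trend removed. The medians of the ribosomal protein and respiratory chain lists were then 0.30 and 0.35, against 0.32 and 0.37 before. The contractile list went from −0.18 to −0.09 and the histone list from 0.39 to 0.35, and both lost their calls (camera adjusted p = 0.072 and 0.062), while the other 10 lists that had passed kept theirs. Reads lost to pseudogenes of ribosomal proteins were not tested.

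Other splits of the libraries were counted for each comparison of at least 3 libraries a group. For siNemp1 at 120 kPa the 10 splits without the block are too few for a share under 0.05 (0 genes in the real split and 1 in the highest other), as are the 4 splits with the block (1 gave as many, with 1224 in the real split and 1 in the highest other). For the average knockdown only the real split gave as many calls. It was 1 of 60 without the block (180 genes against 1 in the highest other) and 1 of 24 with it (1504 against 61). These are the smallest shares that so many splits can give. They argue against a random grouping of these libraries but do not exclude chance, and the replicates may be technical. The 180 calls also became 0 with DESeq2's size factors. With 0 genes in a real split each split gives as many, here 10 of 10 and, for the average stiffness effect, 100 of 100, so these 2 counts say nothing about chance. For the average stiffness effect the highest other split called 2631 genes by setting replicates 2 and 3 at 120 kPa of both treatments apart from all libraries at 10 kPa and replicate 1 at 120 kPa, which points to a structure of the samples.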
